A study of Mus musculus with 15 samples.

How the data were processed

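RNA levels were measured in bone marrow-derived macrophages of C57Bl/6 mice on Illumina bead arrays, with biotin-labelled total RNA per the labels. Cells were exposed to IFNγ, IFNβ or neither for 18 h and then to LPS for 6 h, or not; the labels give its dose as 10 ng/µl, a unit in doubt. The 15 arrays were grouped by their titles into 6 groups of 2 or 3. The slide and position of each array, given in the labels, joined it to its column of values.

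The deposited non-normalized table holds mean bead intensity per probe on a linear scale, before normalization. Scanner software, its version and any background subtraction are not given in the sources used here. A detection p-value stands beside each intensity, per the file headers, and sets the probe against the negative controls of that array. The table lists 15978 probes, and each has a detection p under 0.05 on at least 1 array, which was tested on the file, so dimmer probes were not analysed here. The authors' deposited series values are on a log2 scale. Their near-equal quartiles on every array point to quantile normalization by the authors. The authors' method, with any background correction, is not given in the sources used here. These values served only as an alternative; the lowest correlation of an array with its values computed here was 0.9998 and the largest difference 0.191 log2 units.

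Intensities were background-corrected with limma's normal-exponential model, with the background of each array taken from the detection p-values because negative control probes were not analysed here. An offset of 16 was added, and the arrays were quantile-normalized and put on a log2 scale. A probe was kept if its detection p was under 0.01 on every array of at least 1 group, which left 11117 probes. Of all probes 14994 carried 1 gene symbol, 0 several and 984 none; those without a symbol were left out of the gene tests. The probe with the highest mean log2 level stood for each gene, which gave 7669 genes tested out of 10900 symbols. Median raw intensity per array was 143 to 241, or 1.37 to 1.72 times the background, and 9342 to 11047 probes were detected. The highest signal was 15.4 log2 units, and 49 to 56 genes per group lay within 1 log2 unit of it.

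Limma fitted group means to all 15 arrays at once, with 1 estimate of the spread per gene moderated by empirical Bayes. There were 9 comparisons: each interferon against no interferon without and under LPS, LPS alone against control, IFNγ against IFNβ in both states, and the interaction of each interferon with LPS. Tests were moderated t-tests on both sides, adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. An effect was given as a log2 difference or a fold. For a gene detected on no array of a group, the fold was computed against the lowest detected signal of each array, or the gene's own signal where that was higher, and written as at least that fold. Camera tested 30 fixed gene lists, where at least 5 genes of a list were tested, with its preset correlation of 0.01 and with an estimated correlation, adjusted over the lists within a comparison. With an estimated correlation its degrees of freedom come from the few arrays fitted, and with the preset one from the number of genes. List members were counted as called over all genes and when adjusted over the list alone. Shared calls were set beside the number that independent lists would share and beside 100 simulations of unchanged groups against the shared control arrays.

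The genes named were chosen by a rule. For the 5 comparisons of a treatment with its control these were the 10 called genes with the largest rise and the 10 with the largest fall, with every array of one group above every array of the other. For the 2 comparisons of interferons and the 2 interactions 6 were taken each way, the interactions without the demand of no overlap. Up to 5 genes each way were added whose fold is a lower bound. Of a fixed set of 22 readout genes, 17 were among the genes tested. From each list up to 4 of its largest called and up to 2 of its largest uncalled members could be named. Symbols that only number a transcript were passed over.

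The groups, comparisons, tests, gene lists, the naming rule and the following alternatives were fixed before the data were examined. They are no background correction, an offset of 50, median scaling, cyclic loess, the authors' values, no detection filter, detection p under 0.05, detection on all 15 arrays, all detected probes, trended and robust variances, the replicate number as a block, only the arrays compared, only the slide that holds both groups, an estimated correlation for camera, and leaving out each array in turn. Leaving out 3 doubted arrays together, limma's array weights, camera on the arrays of 1 slide alone, opposite calls on 1 slide or on the compared groups alone, and the overlap of the interferons on fewer arrays were added after seeing the data. Not every alternative was run on every result. Gene lists were rerun only with an estimated correlation, no background correction, median scaling, no detection filter and the replicate block. They were also rerun without the 3 doubted arrays and, for interferon comparisons, on 1 slide alone. For named genes, the tallies and the ranges over the alternatives leave out the fits on 1 slide alone.

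On simulated data with the spread of these arrays, the model recovered 86.6% of log2 changes of 1 for IFNγ, 82.1% for IFNβ and for LPS, 76.1% and 73.1% for IFNγ and IFNβ under LPS, 73.1% and 70.1% for IFNγ against IFNβ without and under LPS, and 31.3% and 19.4% for the interactions of IFNγ and IFNβ. Changes of 2 were recovered at 93.9% to 100%, with 3 to 13 false calls per comparison. The false calls were 6 of 142 calls for IFNγ, 3 of 129 for IFNβ and 10 of 137 for LPS. Under LPS they were 6 of 125 for IFNγ and 13 of 132 for IFNβ. For IFNγ against IFNβ they were 9 of 138 without and 12 of 129 under LPS. The interactions had 7 of 93 for IFNγ and 4 of 81 for IFNβ. Some of these false shares lay above the adjusted p threshold and others below it. Each recovery rate rests on 66 or 67 changed genes in a simulation of its own, with most of the 7669 genes unchanged. Far more genes were called with IFNγ and with LPS, so the rates need not hold there. Differences between the rates were not tested. R 4.3.3 with limma 3.58.1 was used for the tests, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the figures.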

Results

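Macrophages grown from mouse bone marrow in culture were exposed for 18 h to IFNγ, the type II interferon made mainly by T and NK cells, to IFNβ, a type I interferon, or to neither. They were then left alone or given LPS, a component of the outer membrane of Gram-negative bacteria, for 6 h. Whether cells without LPS were kept for those 6 h as well was not recorded here. Comparisons across LPS states may therefore mix LPS with time in culture. The labels give the LPS dose as 10 ng/µl, a unit that is in doubt. No dose of either interferon was recorded here. Differences between the interferons may therefore also be ones of dose, or of the single time of 18 h. RNA levels were measured on Illumina bead arrays, on which each probe reports the brightness of labelled RNA bound to beads. The 15 arrays fell into 6 groups: 3 control arrays, 3 with IFNγ, 2 with IFNβ, 2 with LPS alone, 3 with IFNγ and LPS, and 2 with IFNβ and LPS. The design asks what each interferon did to resting macrophages, what LPS did to unprimed ones, and how priming with either interferon altered the state after LPS.

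The number of arrays limits the precision. The median SE of a log2 difference was 0.183 for IFNγ against control, 0.225 for IFNβ with LPS against LPS alone, and 0.275 and 0.304 for the interactions of IFNγ and of IFNβ with LPS. Median raw intensity ran from 143 to 241 between arrays, 1.37 to 1.72 times the background, and 9342 to 11047 of the 15978 probes were detected. Arrays of a group correlated with each other at r = 0.979 to 0.993 across genes, which are not independent replicates. The labels do not say whether arrays of a group came from separate cultures or animals, so the p-values measure the spread between these arrays, which may be technical. The 7 arrays with LPS lay on one slide and the 8 without on the other, so slide and LPS cannot be told apart. Both groups of every interferon comparison shared a slide, and a slide effect that adds the same amount to every group cancels in the interactions. The fit of all arrays uses 1 spread per gene for both slides. Interferon comparisons fitted on their slide alone called fewer genes with LPS and more without. Calls under LPS thus depend on a spread shared with the arrays without LPS.

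The first principal component, with 69.8% of the variance, parted the arrays with LPS from those without. The second, with 13.5%, placed the 3 IFNγ arrays at 34.7 to 38.4 and the controls at -17.5 to -15.7, while the IFNβ arrays lay beside the controls at -14.0 and -13.7. Array 1 of the IFNγ and LPS group stood at 2.0, between its companions at 18.6 and 19.1 and the LPS arrays at -22.0 and -18.2. Counted over the genes that parted its companions from LPS alone by over 1.5 log2 units, that array lay a median 0.509 of the way on the linear scale for 156 raised genes and 0.479 for 110 lowered genes.

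**Figure D1:**
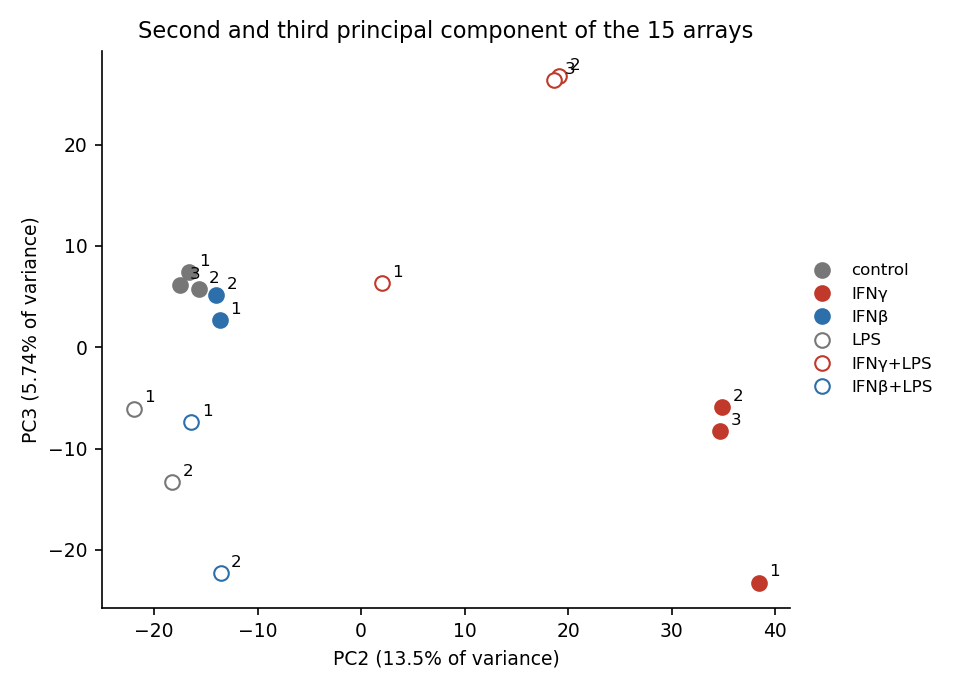
Each point is 1 array, numbered by replicate, at principal components 2 (horizontal, 13.5% of the variance) and 3 (vertical, 5.74%) of log2 intensity. Filled circles are arrays without LPS and open circles arrays with LPS; array 1 of IFNγ and LPS lies apart from the other 2 of its group.

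IFNγ alone (3 arrays against 3 controls) raised the machinery of antigen presentation and the interferon-inducible GTPases. H2-Eb1, a chain of the MHC class II molecules that show peptides to helper T cells, stood at a log2 intensity of 13.5 ± 0.188 (SD, n = 3) against 7.19 ± 0.277 in controls. That is a rise of 80.3-fold (log2 6.33, SE 0.226, adjusted p = 5.12e-11). Gbp2, a guanylate-binding protein of cell-autonomous defence, rose 78.6-fold (log2 6.30, SE 0.116, adjusted p = 9.89e-14), and Calhm6 rose 79.9-fold (SE 0.164 on the log2 scale). Ciita, the master activator of MHC class II genes, was undetected in controls and rose at least 32.4-fold. The chemokine Cxcl9, which draws activated T cells, rose at least 146-fold, and the GTPase Gbp2b at least 184-fold. In the other direction Mmp12, the macrophage elastase, fell 45.7-fold (log2 -5.51, SE 0.679, adjusted p = 2.8e-05). Ednrb, the endothelin B receptor, fell 19.9-fold (log2 -4.31), and Tfrc, the transferrin receptor that takes up iron, fell 7.64-fold (log2 -2.93).

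Every tested member of 2 lists rose with IFNγ. All 13 interferon-inducible GTPases were higher (median log2 4.65, or 4.32 with genes undetected in controls at their bound), among them Gbp3 at 55.0-fold and Igtp at 42.7-fold. All 11 genes of MHC class II presentation rose, with a median of 4.82 either way, including H2-Ab1 (70.5-fold), Cd74, the invariant chain (51.6-fold), and H2-Aa (46.6-fold). MHC class I presentation had 17 of 19 genes up and 0 down (17 adjusted over the list alone, median 1.85), led by the peptide transporter Tap1 at 3.59, Tapbpl at 3.27, the activator Nlrc5 at 3.06 and the immunoproteasome subunit Psmb9 at 2.97 log2 units. The type I interferon antiviral genes had 24 of 32 up and 0 down (25 adjusted over the list alone, median 1.48, or 1.42 at the bounds). Ifit2, which binds viral RNA, rose by 4.73, Ifit3 by 3.17, Mx1 by 3.09 and the ubiquitin-like Isg15 by 3.05 log2 units. In interferon signalling 12 of 20 genes rose and 0 fell (13 and 1 adjusted over the list alone, median 0.78), with the transcription factors Irf1 (10.0-fold) and Irf8 (log2 2.96), and the feedback inhibitors Socs3 (log2 2.78) and Socs1 (at least 5.57-fold). Camera, limma's test of a list against the other genes, gave adjusted p = 1.18e-25 for the GTPases, 2.78e-19 for class II, 7.76e-19 for class I, 8.11e-20 for the antiviral genes and 1.71e-08 for interferon signalling. With an estimated correlation between genes these calls held, at adjusted p = 0.00085, 0.0137, 9.95e-05, 0.0123 and 0.00098.

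Inflammatory mediators moved in part. Of 16 inflammatory cytokines 6 rose and 1 fell with IFNγ, the same counts adjusted over the list alone (median 0.09, or 0.02 at the bounds; camera adjusted p = 0.00791, and adjusted p = 0.0396 with an estimated correlation, a call lost at 0.0940 when the slide's arrays were used alone as well). Tnfsf13b, the B cell survival factor BAFF, rose by 4.25 log2 units, Tnf 3.03-fold (log2 1.60, SE 0.205, adjusted p = 4.1e-05), Il27 at least 2.75-fold, and Il18 by 1.20. Il1b stood at a difference of 0.06 (adjusted p = 0.922), and Il6 was undetected in both groups. The chemokines split into 6 up, with Cxcl10 at 28.3-fold, Ccl8 at log2 4.58 and Ccl5 at log2 4.01, and 4 down among 18 tested, the same adjusted over the list alone (median 0.06, camera adjusted p = 0.0391). That call was lost with an estimated correlation (adjusted p = 0.356), on the 8 arrays of the slide alone (0.0946, or 0.425 with an estimated correlation), and without the 3 doubted arrays described in the closing part (0.154; 0.0238 to 0.425 over the alternatives). Costimulation had 7 of 13 genes up and 0 down (7 adjusted over the list alone, median 1.10, or 0.67 at the bounds). Cd86 rose by 3.77, the PD-1 ligand Cd274 by 3.38 (10.4-fold), Icam1 by 2.51 and Cd40 by 2.30 log2 units. Inflammasome and pyroptosis genes were up in 7 of 18 and down in 0, also over the list alone (median 0.42, or 0.25 at the bounds), with the necroptosis effector Mlkl at 2.22, Casp4, the sensor of cytosolic LPS, at 1.77 and the adaptor Pycard at 1.32. Camera gave adjusted p = 1.27e-06 for costimulation and 0.000357 for the inflammasome list, and 0.0137 for each of them with an estimated correlation.

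Sterol synthesis fell with IFNγ: 13 of 18 genes were down and 0 up (13 and 2 adjusted over the list alone, median -0.97, camera adjusted p = 4.11e-05, adjusted p = 0.144 with an estimated correlation, and 0.0240 with one on the slide's arrays alone). Cyp51 changed by -1.76, Hsd17b7 by -1.71, Hmgcs1, which makes the precursor of mevalonate, by -1.64 and the feedback regulator Insig1 by -1.58 log2 units. Glycolysis rose in 10 of 19 genes and fell in 0 (10 and 1 adjusted over the list alone, median 0.59, camera adjusted p = 4.11e-05, adjusted p = 0.0396 with an estimated correlation, lost at 0.0773 with one on the slide's arrays alone). The phosphofructokinase Pfkp rose by 2.26, the transcription factor Hif1a by 2.02 and the hexokinase Hk3 by 1.21. Macrophage identity genes were down in 7 of 19 and up in 1, also over the list alone (median -0.24, camera adjusted p = 0.0188). Besides Mmp12 these included Ctsl (at least 3.26-fold lower), Cd9 (-1.94) and the transcription factor Maf (-1.04). The list's call was lost with an estimated correlation (adjusted p = 0.331) and with median scaling (0.110; 0.00376 to 0.331 over the alternatives).

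Lists that camera did not call with IFNγ still held called members going both ways. Cholesterol efflux had 2 of 11 up and 4 down, with Ch25h, which makes an oxysterol, up at least 37.4-fold and the desaturase Scd1 down by 2.24 log2 units. Its median of -0.42 and its mean of 0.08 differed in sign (adjusted p = 0.45). NF-kB targets and feedback genes had 4 of 25 up and 4 down (5 and 4 adjusted over the list alone, median 0.07, adjusted p = 0.38), the rises including Birc2 by 1.01 and Nfkbie by 0.92. Nitric oxide and oxidant enzymes had 3 of 16 up and 4 down (4 and 6 over the list alone, median 0.13, or 0.01 at the bounds, adjusted p = 0.802). Ass1, which regenerates arginine, rose by 1.70, the haem oxygenase Hmox1 changed by -1.15 and Srxn1 by -1.06. Alternative activation markers split into 4 up and 5 down of 14 (5 and 6 over the list alone, median 0.20, or 0.06 at the bounds, adjusted p = 0.421), the lectins Mgl2 and Clec10a rising by 2.24 and 2.13 and Stab1 changing by -1.87. Of 22 anti-inflammatory factors 6 rose and 6 fell (8 and 7 over the list alone, median -0.06 and mean 0.17, adjusted p = 0.45). Among them Anxa1 changed by -2.10, Axl rose by 2.0, and Il10 rose 3.54-fold (log2 1.82, SE 0.214, adjusted p = 1.79e-05). The Toll-like receptor pathway had 5 of 26 up and 3 down (6 and 4 over the list alone, median 0.11, adjusted p = 0.375), with the LPS coreceptor Cd14 at -2.23 and Tlr4 itself up 1.55-fold. Fc, complement and scavenger receptors had 6 of 18 up and 3 down (7 and 3 over the list alone, median 0.09, adjusted p = 0.0932, but 0.0399 with median scaling and up to 0.498 over the alternatives). Fcgr1, the high-affinity IgG receptor, rose by 2.34 while C5ar1 changed by -1.88.

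With IFNγ cell cycle genes had 1 of 34 up and 3 down (median -0.05, adjusted p = 0.997), the TCA cycle and respiratory chain 5 of 31 up and 2 down (median 0.05, adjusted p = 0.414), and unfolded protein and heat shock genes 1 of 19 up and 5 down (median -0.21, adjusted p = 0.486), each with the same counts adjusted over the list alone. Reference genes had 1 of 9 down, the glucuronidase Gusb at -0.83 (median -0.20, adjusted p = 0.747). Among markers of other cell types, dendritic cell genes rose in 3 of 7 (median 0.65, adjusted p = 0.00791, adjusted p = 0.134 with an estimated correlation). They were Cd1d1 by 1.68, Batf3 by 1.52 and Clec9a at least 1.65-fold, beside the rise of the MHC class II and costimulation genes. Which cells carried the RNA of such markers was not measured. Neutrophil genes had 1 of 10 up and 1 down, the latter Mmp9 at least 7.58-fold lower (median 0.26, or 0.11 at the bounds, but mean -0.09, adjusted p = 0.604). T and NK cell genes had 0 of 4 up and 2 down (Cd28 at -1.89), and B cell genes 1 of 3 down (Blnk at -1.36). Erythroid and megakaryocytic markers had 0 of 4 called, fibroblast and stromal markers 0 of 2, and the 1 mast cell and basophil gene tested was called higher; these short lists had no camera test. By limma at unadjusted p under 0.05, 2839 genes passed in this comparison.

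By limma 2001 of the 7669 genes tested were called with IFNγ, 884 higher and 1117 lower, at an adjusted p under 0.05. Cyclic loess in place of quantile normalization turned that split to 1090 higher and 858 lower. On the 8 arrays of the slide alone 2233 genes were called, and with array weights 3072.

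**Figure D2:**
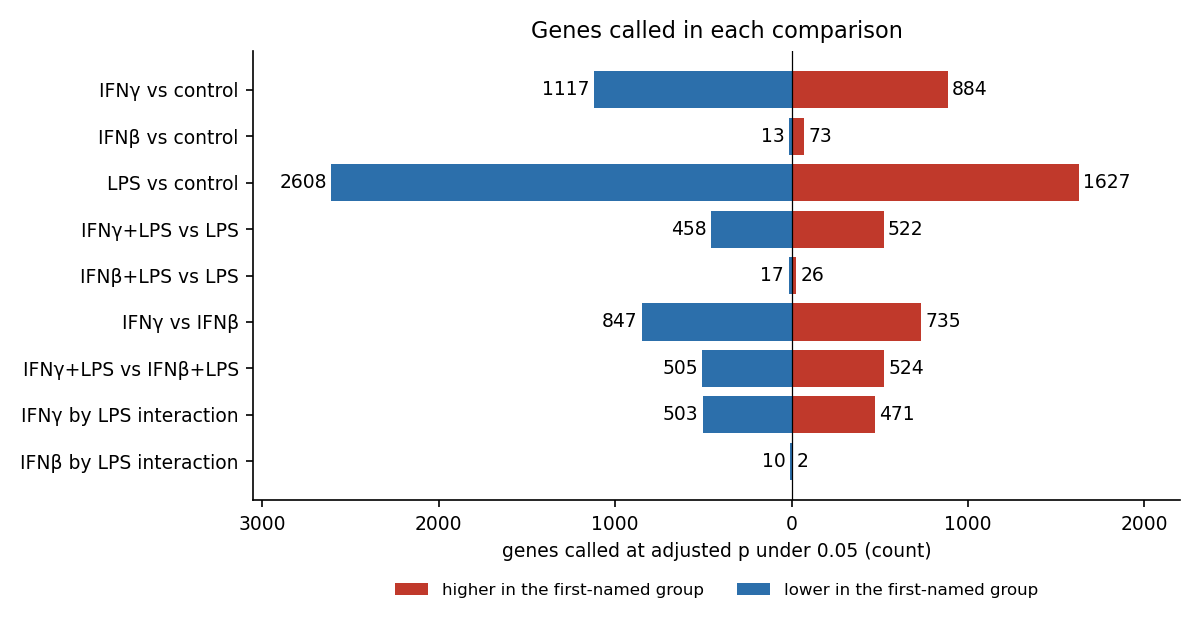
Bars give the number of genes called by limma at an adjusted p under 0.05 in each of the 9 comparisons, to the right for genes higher in the first-named group or with a positive interaction and to the left for lower or negative. LPS called 1627 higher and 2608 lower, and the IFNβ by LPS interaction 2 positive and 10 negative.

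IFNβ alone (2 arrays against 3 controls) raised a set of interferon-stimulated genes, with fewer genes called than for IFNγ. The chemokine Ccl5, which recruits T cells and monocytes, rose 64.2-fold (log2 6.00, SE 0.184, adjusted p = 1.13e-10). Ifit3 rose 7.54-fold (log2 2.91, SE 0.385, adjusted p = 0.00116), the acute-phase gene Saa3 7.49-fold, Ly6e 6.99-fold (SE 0.229, adjusted p = 2.51e-05) and Ifit2 5.93-fold. The scavenger receptor Marco rose 4.21-fold, Oasl2, of the 2'-5' oligoadenylate synthetase family, 4.2-fold, Phf11a 3.70-fold, and Irf7, a transcription factor that amplifies type I interferon, at least 3.75-fold. Gbp2 rose 2.31-fold (log2 1.21, adjusted p = 0.000176). Values for Tnf (-0.25, adjusted p = 0.972), Il10 (0.75, adjusted p = 0.266) and Irf1 (0.17, adjusted p = 0.922) did not pass the test. Cxcl10 stood at 1.20 (adjusted p = 0.485), and without IFNβ array 1 at 2.34 (adjusted p = 0.0132; 0.0132 to 0.999 over the alternatives). Psat1, an enzyme of serine synthesis, fell 2.51-fold (log2 -1.33, adjusted p = 0.00392), but was uncalled without IFNβ array 1 (0.0839; 0.000242 to 0.0839 over the alternatives).

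The type I interferon antiviral genes had 19 of 32 up and 0 down with IFNβ, and 26 adjusted over the list alone (median 1.0, or 0.94 at the bounds; camera adjusted p = 7.58e-51, adjusted p = 0.000777 with an estimated correlation). Among the GTPases 6 of 13 rose and 0 fell (8 over the list alone, median 0.79, adjusted p = 1.3e-15, 0.00393 estimated), including Ifi47 by 1.43 and Gvin1 by 1.32. MHC class I presentation had 3 of 19 up (8 over the list alone, median 0.49, adjusted p = 4.4e-11, adjusted p = 0.000777 with an estimated correlation), among them H2-T23 by 1.12, a ligand of NK cell receptors. In MHC class II presentation 0 of 11 genes were called by limma and 3 over the list alone; its median of 0.26 was called by camera (adjusted p = 0.000223) but not with an estimated correlation (adjusted p = 0.223). Chemokines had 4 of 18 up and 0 down (5 over the list alone, median 0.16, adjusted p = 1.13e-06, adjusted p = 0.0322 with an estimated correlation, lost at 0.0802 with one on the slide's 8 arrays alone), with Ccl8 by 1.75 beside Ccl5. Fc, complement and scavenger receptors had 3 of 18 up (4 over the list alone, median 0.20, adjusted p = 0.000117, 0.0123 estimated, lost at 0.122 with the slide alone as well). Interferon signalling (median 0.17) and the inflammasome list (median 0.27, or 0.22 at the bounds) were called at adjusted p = 0.00618 and 0.00199, each at 0.0322 with an estimated correlation, on 0 and 1 called genes, and on 0 in both with the slide alone. With an estimated correlation on the slide alone both calls were lost (0.0802 and 0.0590).

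Sterol synthesis was lower with IFNβ as a list: 1 of 18 genes was called down, on the slide alone 3, and 6 over the list alone (median -0.50, adjusted p = 1.12e-09, adjusted p = 0.0322 with an estimated correlation). The called gene was Insig1 at -1.03 (adjusted p = 0.0282). It was uncalled without control array 1 (0.108) or 3 (0.125), without IFNβ array 1 (0.436) or 2 (0.117), and with cyclic loess (0.0523), within 0.00166 to 0.436 over the alternatives. Glycolysis genes were also lower as a list (1 of 19 down, on the slide alone 0, 2 over the list alone, median -0.19, adjusted p = 2.34e-05, 0.0322 estimated), as were unfolded protein and heat shock genes (2 of 19 down and 1 up, 3 and 1 over the list alone, median -0.23, adjusted p = 0.000138, 0.0106 estimated). Both calls were lost with an estimated correlation on the slide's arrays alone (0.0802 and 0.0541), where that of sterol synthesis held (0.00878). The cell cycle list (median -0.20, 0 of 34 called) passed at adjusted p = 0.000117 but not with an estimated correlation (adjusted p = 0.156). The Toll-like receptor list (median 0.12, 0 of 26 called) passed at 0.0459, with 0.245 at an estimated correlation and 0.0907 with median scaling, within 0.0131 to 0.245 over the alternatives. For macrophage identity the median was -0.01 (adjusted p = 0.878), and NF-kB targets stood at -0.11, or -0.06 at the bounds (adjusted p = 0.107), with 0 genes called in either list.

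IFNβ changed 86 genes by limma, 73 higher and 13 lower, with 632 at unadjusted p under 0.05. On the slide's 8 arrays alone 92 were called, with array weights 195, and without the 3 doubted arrays 153. Leaving out 1 array gave 54 without control array 2, 56 without control array 3, 34 without IFNβ array 1 and 31 without IFNβ array 2.

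**Figure D3:**
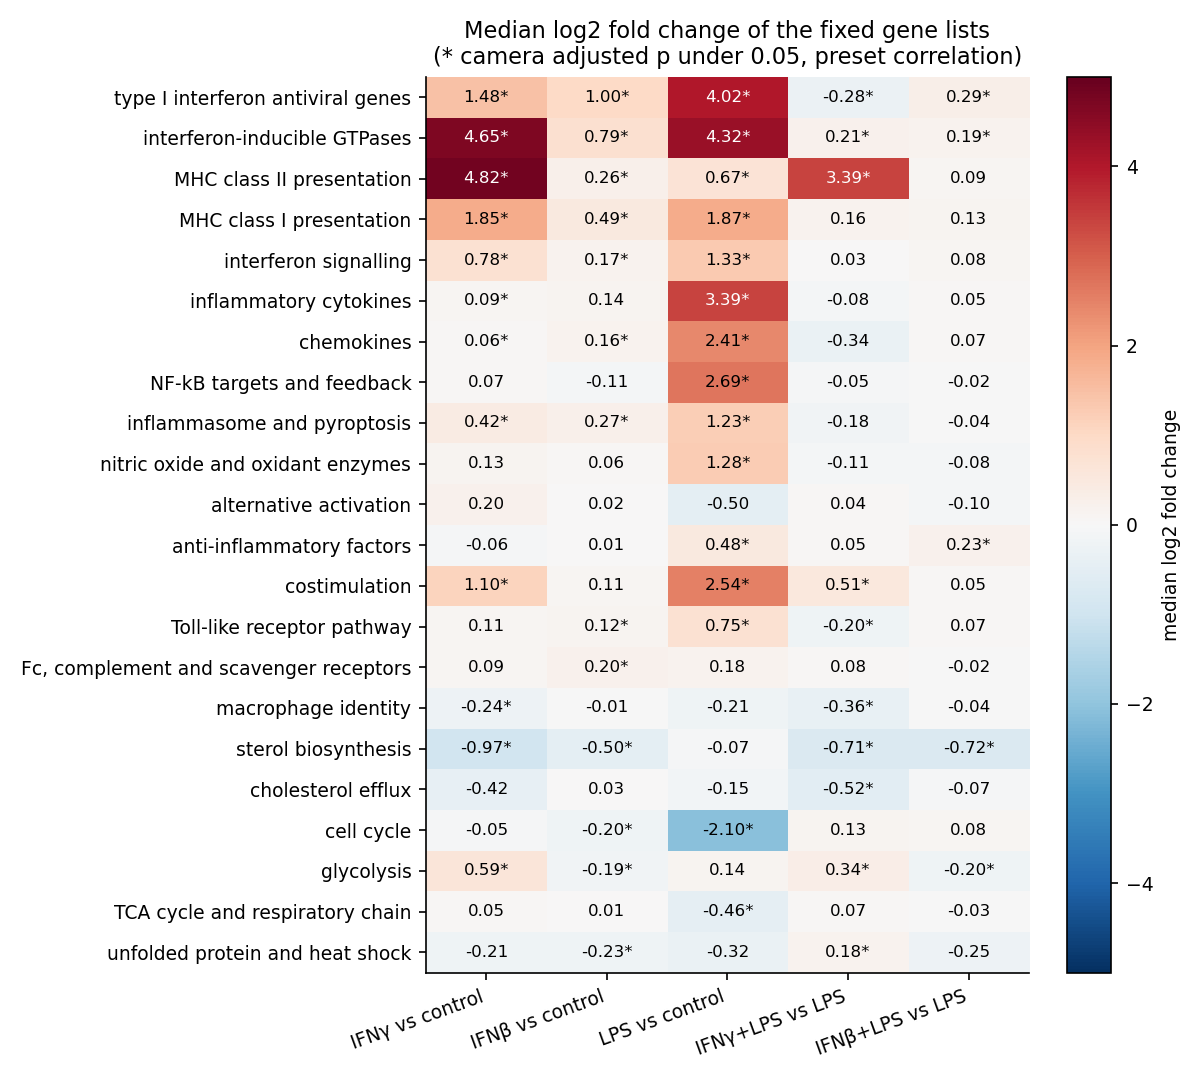
Each cell gives the median log2 fold change of a fixed gene list (vertical) in 1 of the 5 comparisons of a treatment with its control (horizontal), red for higher and blue for lower; a star marks camera adjusted p under 0.05 with the preset correlation. MHC class II presentation stands at 4.82 for IFNγ alone and 3.39 for IFNγ under LPS, and at 0.26 for IFNβ alone.

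Set against each other without LPS (3 arrays against 2), IFNγ stood above IFNβ for Cxcl9 by 87.5-fold (log2 6.45), H2-Eb1 by 46.8-fold, and H2-Ab1 and Gbp5 by 45.8-fold each. Gbp2b was at least 189-fold and Ciita at least 33.1-fold higher with IFNγ, and Tnf 3.60-fold higher (log2 1.85). Ednrb was 26.4-fold, Mmp12 22-fold and Saa3 9.78-fold lower. All 13 GTPases were higher with IFNγ (median 4.19, or 4.0 at the bounds, adjusted p = 6.39e-26, 0.000816 estimated). So were 10 of 11 MHC class II genes (11 over the list alone, median 4.59, adjusted p = 1.15e-19, 0.0134 estimated), 15 of 19 class I genes (17 over the list alone, median 1.16, adjusted p = 3.59e-15, 0.000245 estimated), 13 of 19 glycolysis genes (14 up and 1 down over the list alone, median 0.71, adjusted p = 5.25e-09, 0.0133 estimated) and 7 of 13 costimulation genes (median 0.69, adjusted p = 9.92e-07, 0.0134 estimated). The antiviral genes had 11 of 32 higher with IFNγ and 2 lower (12 and 4 over the list alone, median 0.39, adjusted p = 0.00236, adjusted p = 0.348 with an estimated correlation). Sterol synthesis genes differed with a median of -0.56, or -0.49 at the bounds (7 down and 2 up of 18, on the slide alone 8 and 1, 10 and 2 over the list alone, adjusted p = 0.057, but 0.0153 on the slide's arrays alone, and called with median scaling, with no detection filter and without the 3 doubted arrays, within 0.00687 to 0.487 over the alternatives). By limma 1582 genes differed, 735 higher and 847 lower with IFNγ. That split turned with cyclic loess (825 higher, 678 lower) and without IFNβ array 1 (466 and 396) or 2 (459 and 403). The count was 1759 on the slide's arrays alone, 2610 with array weights, and 862 without IFNβ array 1 or without array 2.

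LPS alone (2 arrays against 3 controls) brought the largest shifts. Cxcl10, a chemokine induced by interferons and NF-kB, rose 644-fold (log2 9.33, SE 0.485, adjusted p = 1.14e-09), the cytokine Il1b 383-fold (SE 0.396), Ccl5 279-fold, Saa3 224-fold and the feedback inhibitor Socs3 183-fold. Tnf rose 62.7-fold (log2 5.97, SE 0.229), Il6 at least 25.9-fold, Il27 at least 41.0-fold, Nos2, the inducible nitric oxide synthase, at least 15.3-fold and the anti-inflammatory cytokine Il10 9.93-fold. The activation marker Cd69 was at least 479-fold and Cxcl9 at least 182-fold higher. Slc40a1, the iron exporter ferroportin, fell 33.9-fold (log2 -5.08, SE 0.209, adjusted p = 1.17e-10). Gadd45a fell 23.9-fold, St6gal1, a sialyltransferase, 20.5-fold, Sesn1 20.3-fold and the ERK phosphatase Dusp6 19.6-fold, and the chemokine receptor Cxcr4 was at least 14.4-fold lower.

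All 25 tested NF-kB targets rose with LPS (median 2.69, adjusted p = 1.2e-17, 0.000728 estimated), with Traf1 at 6.21, Nfkbiz at 5.35 and the inhibitor Nfkbia at 4.30 log2 units. Inflammatory cytokines were up in 13 of 16 (median 3.39, or 2.82 at the bounds, adjusted p = 1.87e-10) and chemokines in 15 of 18 with 1 down (median 2.41, adjusted p = 1.86e-08). Interferon-stimulated lists rose as well: antiviral genes in 30 of 32 (median 4.02, or 3.77 at the bounds, adjusted p = 6.23e-25) with Mx2 at least 77.0-fold and Mx1 172-fold, and all 13 GTPases (median 4.32, or 4.08 at the bounds, adjusted p = 4.17e-14) with Gbp3 at 113-fold. MHC class I presentation had 16 of 19 up and 1 down (median 1.87, adjusted p = 2.41e-09), interferon signalling 16 of 20 up and 1 down (median 1.33, adjusted p = 3.14e-08), and costimulation 11 of 13 up (median 2.54, adjusted p = 2.41e-09), Cd40 by 7.04. The counts adjusted over each list alone were the same. With an estimated correlation all 8 of these lists stayed called, the highest adjusted p being 0.0168 for the chemokines. MHC class II had 7 of 11 up (median 0.67, adjusted p = 0.00591), a call lost with an estimated correlation (adjusted p = 0.328).

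The inflammasome list had 11 of 18 up and 2 down (median 1.23, or 0.99 at the bounds, adjusted p = 4.1e-05, 0.00599 estimated), Casp4 rising 12.8-fold. Nitric oxide and oxidant enzymes had 10 of 16 up and 3 down (median 1.28, adjusted p = 0.00108, 0.0132 estimated), the Toll-like receptor pathway 17 of 26 up and 4 down (median 0.75, adjusted p = 4.1e-05, 0.0356 estimated) and anti-inflammatory factors 11 of 22 up and 3 down (median 0.48, adjusted p = 0.0034, 0.0168 estimated), with the phosphatase Dusp2 at 4.53. Tlr4 differed by -0.56, while its other probe differed by 0.33. Cell cycle genes fell in 30 of 34 and rose in 1 (median -2.10, or -1.82 at the bounds, adjusted p = 3.89e-10, 0.0203 estimated), among them Uhrf1 at -3.50, the anaphase activator Cdc20 at -3.34 and the thymidine kinase Tk1 at -3.01. The TCA cycle and respiratory chain had 18 of 31 down and 2 up (19 and 2 over the list alone, median -0.46, adjusted p = 0.0361), with Idh1 at -2.32; that call was lost with an estimated correlation (adjusted p = 0.123) and with median scaling (0.323; 0.0135 to 0.323 over the alternatives).

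Several lists split with LPS and were not called by camera. Alternative activation had 3 of 14 up and 7 down (median -0.50, or -0.19 at the bounds, adjusted p = 0.571), with the nuclear receptor Pparg at -3.39. Glycolysis had 6 of 19 up and 8 down (7 and 9 over the list alone, median 0.14, adjusted p = 0.674), unfolded protein and heat shock 5 of 19 up and 8 down (5 and 9 over the list alone, median -0.32, adjusted p = 0.646), macrophage identity 4 of 19 up and 7 down (median -0.21, adjusted p = 0.674), sterol synthesis 2 of 18 up and 4 down (median -0.07, test direction up, adjusted p = 0.922) and cholesterol efflux 2 of 11 up and 3 down (median -0.15, mean 0.22, adjusted p = 0.776). Fc, complement and scavenger receptors had 5 of 18 up and 5 down (median 0.18, adjusted p = 0.151, but 0.0236 with median scaling and up to 0.255 over the alternatives). The lists of markers for other cell types do not show which cells carried the RNA, and macrophages may have done so. On the neutrophil list 3 of 10 genes were up and 1 down (Lcn2 by 4.44, median 0.41, or 0.21 at the bounds, camera adjusted p = 0.0775). Dendritic cell genes had 3 of 7 up (Bst2 by 2.01, median 0.29, adjusted p = 0.0838, and 0.0285 with no detection filter, within 0.0285 to 0.267 over the alternatives). Bst2 is also on the list of type I interferon antiviral genes. Hdc, on the mast cell and basophil list, makes histamine and rose at least 63.3-fold. Reference genes had 2 of 9 up and 4 down (median -0.44, camera adjusted p = 0.571).

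With LPS limma called 4235 genes, 1627 higher and 2608 lower. The median difference over all genes was -0.17, against -0.01 with cyclic loess and -0.03 with median scaling, and cyclic loess called 1969 higher and 2027 lower, so directions of small changes with LPS are relative to that shift.

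IFNγ with LPS was set against LPS alone (3 arrays against 2) to ask what priming adds under LPS. MHC class II genes and a group of IFNγ targets stayed above LPS alone: Gbp2b rose 46.7-fold (log2 5.55, SE 0.248, adjusted p = 1.69e-08), H2-Eb1 31.2-fold, H2-Aa 21.9-fold, the ribonuclease Rnase6 17.4-fold, the kynureninase Kynu 17.3-fold, Cd74 14.6-fold and Ciita 12.7-fold. Ido1, which degrades tryptophan, was at least 10.0-fold and the ubiquitin-like Ubd at least 32.4-fold higher. Cxcl9 rose 4.81-fold, Socs1 3.31-fold, Nos2 3.01-fold (log2 1.59, adjusted p = 0.00401) and Il27 2.10-fold (log2 1.07, adjusted p = 0.000714). Tnf (-0.03, adjusted p = 0.948), Cxcl10 (-0.38, adjusted p = 0.668) and Casp4 (-0.12) did not pass. Il10 differed by -0.64 (adjusted p = 0.0981), and by -0.86 without IFNγ and LPS array 1 (adjusted p = 0.0151); without the 3 doubted arrays, without background correction or with array weights it was also called (0.0184, 0.0381 and 0.0393; 0.0151 to 0.474 over the alternatives).

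Genes lower with IFNγ under LPS were less settled. Edn1, the endothelin precursor, was lower by 8.18-fold (log2 -3.03, adjusted p = 0.00455), Cav1, the coat protein of caveolae, by 6.12-fold (adjusted p = 0.00443), Isg20, an antiviral exonuclease, by 4.79-fold and Mx2 by 2.59-fold (log2 -1.37, adjusted p = 0.00524). Fitted on the compared groups alone, these 4 were not called, at adjusted p = 0.103, 0.103, 0.0906 and 0.0819, the highest over their alternatives; on the slide's 7 arrays alone Edn1 stood at 0.0695 and Mx2 at 0.0509. Il1b was lower by 3.31-fold (log2 -1.73, adjusted p = 0.0117). Without LPS array 1 or 2 or IFNγ and LPS array 3 it was not called (0.0708, 0.0673 and 0.0506), nor on the slide's arrays alone (0.0899), within 7.92e-06 to 0.123 over the alternatives.

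**Figure D4:**
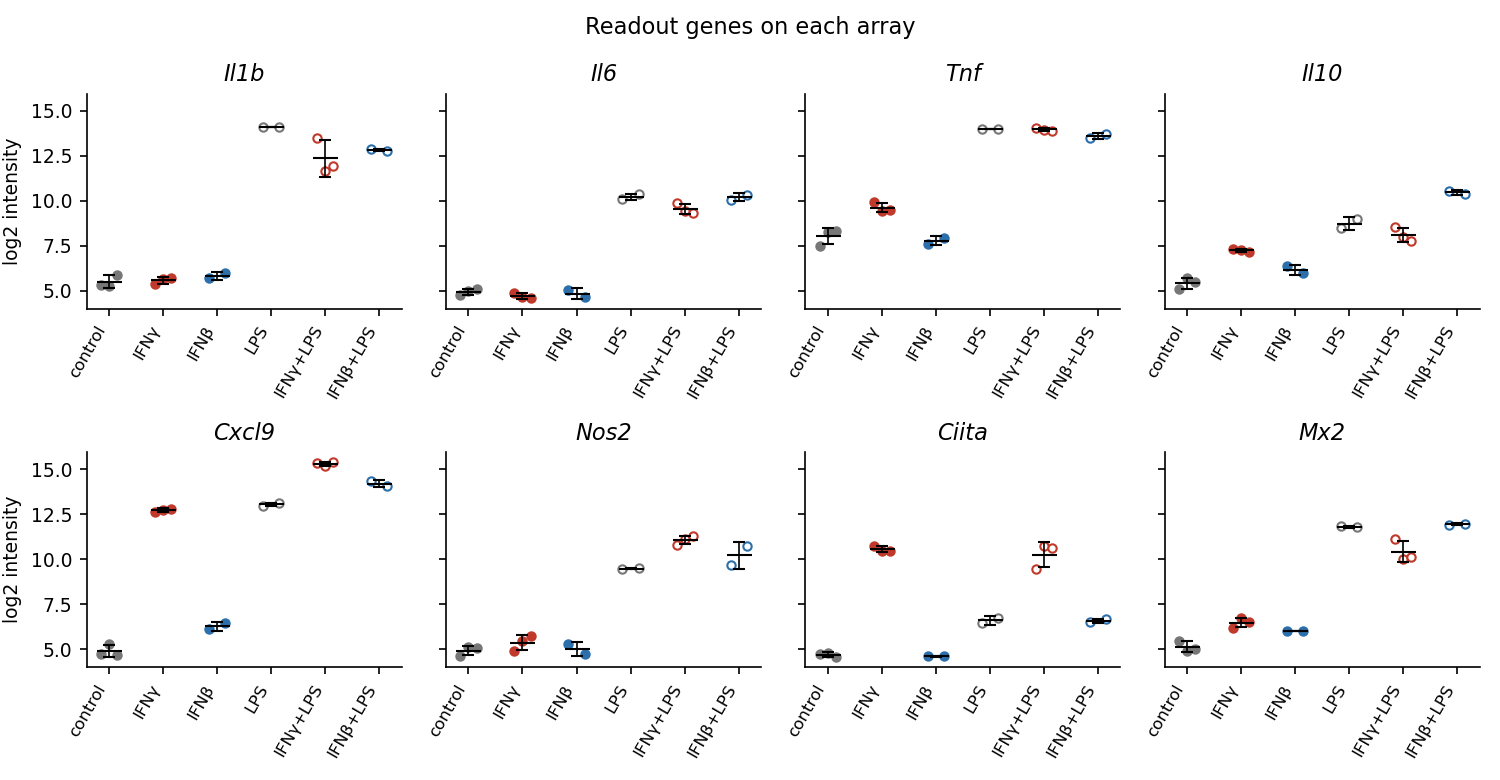
Log2 intensity of 8 readout genes (vertical) on each of the 15 arrays by group (horizontal), with the group mean and SD as bars; open circles are arrays with LPS. Ciita stands high with IFNγ in both states, and in Il1b and Mx2 array 1 of IFNγ and LPS lies nearer to LPS alone than the other 2 arrays do.

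MHC class II presentation was the list that moved most with IFNγ under LPS: 10 of 11 genes were up (11 over the list alone, median 3.39, adjusted p = 1.74e-22, adjusted p = 0.0453 with an estimated correlation, and uncalled at 0.361 with one on the slide's 7 arrays alone, where 10 genes were up as well). The other list calls of this comparison were lost with an estimated correlation on all arrays, and most had fewer called members on the slide alone. Costimulation had 5 of 13 up and 1 down, on the slide alone 3 and 0 (7 and 1 over the list alone, median 0.51, adjusted p = 0.00333, 0.161 estimated), with Cd86 at 1.37, the receptor Slamf1 at 1.31 and Cd80 at 1.16. Glycolysis had 5 of 19 up, on the slide alone 2 (8 over the list alone, median 0.34, adjusted p = 0.00164, 0.161 estimated), Pfkp by 1.57 and Hif1a by 1.47. Sterol synthesis had 9 of 18 down, on the slide alone 2 (11 down and 1 up over the list alone, median -0.71, adjusted p = 9.38e-06, 0.165 estimated), Mvd at -1.38 and Hmgcs1 at -1.17, both uncalled on the compared groups alone (0.0637 and 0.0861, the highest over their alternatives). Macrophage identity had 5 of 19 down, on the slide alone 1 (10 over the list alone, median -0.36, adjusted p = 5.49e-05, 0.161 estimated).

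Of the antiviral genes 7 of 32 were called lower with IFNγ under LPS and 0 higher, also over the list alone, but on the slide alone 1 lower (median -0.28, adjusted p = 0.0069, 0.306 estimated). Of the GTPases 4 of 13 were higher, on the slide alone too (5 over the list alone, median 0.21, adjusted p = 0.0195, 0.253 estimated), Gbp11 by 1.45. The Toll-like receptor pathway had 5 of 26 down, on the slide alone 0 (median -0.20, adjusted p = 0.0195, 0.253 estimated), and cholesterol efflux 2 of 11 down, on the slide alone 1 (4 down and 1 up over the list alone, median -0.52, or -0.29 at the bounds, adjusted p = 0.0195, 0.221 estimated). Unfolded protein genes had 3 of 19 up, on the slide alone 0 (median 0.18, adjusted p = 0.0446, adjusted p = 0.161 with an estimated correlation and 0.0538 without the 3 doubted arrays, within 0.0296 to 0.361 over the alternatives). Chemokines had 1 of 18 up and 5 down, on the slide alone 1 and 0 (1 and 8 over the list alone, median -0.34, adjusted p = 0.0692), and were called without background correction, with median scaling, with no detection filter and without the 3 doubted arrays (0.0143 to 0.440 over the alternatives). Dendritic cell markers were mixed beside the class II genes: 4 of 7 were up, including Batf3 by 1.52 and Ccr7 at least 1.54-fold, and 1 was down, Fscn1 at -1.63 (median 0.96, or 0.63 at the bounds, adjusted p = 0.0687). Nitric oxide and oxidant enzymes had 4 of 16 up and 2 down, on the slide alone 4 and 0 (4 and 5 over the list alone, adjusted p = 0.883); their median of -0.11 and mean of 0.28 differed in sign.

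Limma called 980 genes between IFNγ with LPS and LPS alone, 522 higher and 458 lower. The count was 305 (237 higher, 68 lower) on the slide's 7 arrays and 203 on the compared groups, and 1982 (930 higher, 1052 lower) without the 3 doubted arrays. The split also turned without IFNγ and LPS array 1 (698 and 802), with array weights (676 and 730) and with trended robust variances (49.8% higher). Leaving out 1 array gave 404 and 469 without LPS array 1 and 2, and 1500, 508 and 523 without IFNγ and LPS array 1, 2 and 3. On the slide's arrays alone the camera calls of this comparison held with the preset correlation and were lost with an estimated one (each at adjusted p = 0.361).

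IFNβ with LPS gave few called genes against LPS alone (2 arrays against 2). The median SE of 0.225 was the largest of the comparisons with a control. Il10 was higher by 3.32-fold (log2 1.73, SE 0.262, adjusted p = 0.017), and Mvd, of the mevalonate pathway, was lower by 3.13-fold (log2 -1.65, adjusted p = 0.0192). Gna11, a G protein subunit, was at least 1.58-fold lower (adjusted p = 0.00406). None of these calls held on the slide's 7 arrays alone, at adjusted p = 0.213 for Il10, 0.244 for Mvd and 0.164 for Gna11. On the 4 compared arrays the adjusted p was 0.307 for Il10, Mvd and Gna11, the highest over their alternatives, which began at 0.000296, 0.00312 and 0.00516. Without LPS array 1 Il10 and Mvd stood at 0.133 and 0.157, and without IFNβ and LPS array 1 at 0.0664 and 0.0854. Tnf (-0.40, adjusted p = 0.586), Il6 (-0.04, adjusted p = 0.967), Nos2 (0.74, adjusted p = 0.38) and Mx2 (0.15, adjusted p = 0.895) did not pass. Il1b stood at -1.27 (adjusted p = 0.23), and was called without the 3 doubted arrays (0.0453; 0.0453 to 0.545 over the alternatives).

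Sterol synthesis was the list that fell furthest with IFNβ under LPS: 3 of 18 genes were down, Mvd among them, on the slide alone 0, and 12 over the list alone (median -0.72, adjusted p = 2.78e-09, adjusted p = 0.183 with an estimated correlation). The antiviral list (median 0.29, adjusted p = 0.000286), the GTPases (median 0.19, adjusted p = 0.0305) and glycolysis (median -0.20, adjusted p = 0.0377) passed camera with 0 genes called by limma, none over the list alone, and an adjusted p = 0.347 each with an estimated correlation. Anti-inflammatory factors had 1 of 22 up, Il10, and on the slide alone 0 (median 0.23, adjusted p = 0.0377, 0.183 with an estimated correlation). Without the 3 doubted arrays the GTPases and the anti-inflammatory factors stood at 0.251 and 0.237, and with median scaling the latter at 0.0675; the alternatives ran from 0.0109 to 0.574 and from 0.0196 to 0.573. On the slide's arrays alone these 5 list calls held with the preset correlation, and with an estimated one none did (lowest adjusted p = 0.573). In all, 43 genes were called by limma, 26 higher and 17 lower, with 945 at unadjusted p under 0.05. On the slide's 7 arrays limma called 0 genes (679 at unadjusted p under 0.05), and on the 4 compared arrays 0 (654 unadjusted). If no gene differed, a share of 0.05 of the 7669 genes would pass unadjusted, and each unadjusted count here was above that share. So few calls in so small a comparison do not show that few genes differed. Median scaling called 16 higher and 17 lower, and leaving out the 3 doubted arrays 53 and 61. The count was 65 without background correction, 28 with no detection filter, 11 among genes detected on all 15 arrays, 16 with array weights and 114 without the 3 doubted arrays, and 1, 24, 13 and 15 without LPS array 1, LPS array 2, IFNβ and LPS array 1, and IFNβ and LPS array 2.

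Under LPS, IFNγ stood above IFNβ (3 arrays against 2) for Ubd by 35.9-fold, H2-Eb1 by 28.7-fold, Gbp2b by 27.7-fold, H2-Ab1 by 17.9-fold and Cxcl9 by 2.18-fold. It stood below IFNβ for Il10 by 5.17-fold (log2 -2.37, SE 0.239, adjusted p = 3.31e-05) and for Fos, a subunit of the AP-1 transcription factor, by 5.10-fold (log2 -2.35). Apol9b was at least 3.95-fold lower with IFNγ, and Mx2 2.88-fold lower (log2 -1.53), the latter uncalled on the compared groups alone (0.0635, the highest over its alternatives). MHC class II had 10 of 11 higher with IFNγ (median 3.48, adjusted p = 1.13e-19), glycolysis 8 of 19 (11 over the list alone, median 0.44, adjusted p = 1.61e-06), and unfolded protein genes 6 of 19 and on the slide alone 1 (10 up and 1 down over the list alone, median 0.37, adjusted p = 0.00264), each at adjusted p = 0.0473 with an estimated correlation and uncalled at 0.259 with one on the slide's arrays alone. The antiviral genes had 13 of 32 lower and 0 higher, on the slide alone 7 lower (17 over the list alone, median -0.51, adjusted p = 2.7e-08) and the Toll-like receptor pathway 7 of 26 lower, on the slide alone 2 (10 over the list alone, median -0.27, adjusted p = 0.000763), both at adjusted p = 0.136 with an estimated correlation. GTPases (1 of 13 higher, on the slide alone 0, median 0.16, adjusted p = 0.477) and sterol synthesis (0 of 18 called by limma or over the list alone, median -0.05, or 0.01 at the bounds, adjusted p = 0.875) did not pass. Limma called 1029 genes, 524 higher and 505 lower with IFNγ, median scaling 670 and 396, and cyclic loess 463 and 536. The count was 403 on the slide's 7 arrays, 187 on the compared groups, 593 without IFNγ and LPS array 2 and likewise without array 3, and 520 without IFNβ and LPS array 2.

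The interaction asks whether the IFNγ difference itself changed with LPS. For Gbp3 the difference under LPS was smaller by an interaction of -6.21 log2 units (SE 0.247, adjusted p = 1.42e-09), for Calhm6 by -6.16, Gbp2 by -6.08 and Cxcl10 by -5.20 (SE 0.651). The interaction was -2.91 for Cd274, -2.46 for Il10 and -1.63 for Tnf. Bhlhe40, a transcription factor of cytokine control, had a positive interaction of 3.56 (SE 0.312, adjusted p = 3.67e-06), as had the cell cycle inhibitor Cdkn2b (3.32), Ednrb (3.27) and the lipid droplet gene Hilpda (3.15). GTPases had a negative interaction in 12 of 13 genes (median -3.78, adjusted p = 6.61e-26, 0.000818 estimated), antiviral genes in 23 of 32 (26 over the list alone, median -2.21, adjusted p = 1.64e-25, 0.00525 estimated), and MHC class I genes in 14 of 19 (15 over the list alone, median -1.68, adjusted p = 1.84e-16, 0.000173 estimated). MHC class II had 6 of 11 negative (median -1.09, adjusted p = 3.51e-05, adjusted p = 0.215 with an estimated correlation), and chemokines 8 of 18 negative and 2 positive (10 and 3 over the list alone, median -1.0, adjusted p = 3.85e-05, adjusted p = 0.0762 with an estimated correlation). Medians of interactions include genes undetected in a group, whose fitted values are not bounds. Limma called 974 genes, 471 positive and 503 negative; the count was 640 without LPS array 2 and 1464 with array weights.

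**Figure D5:**
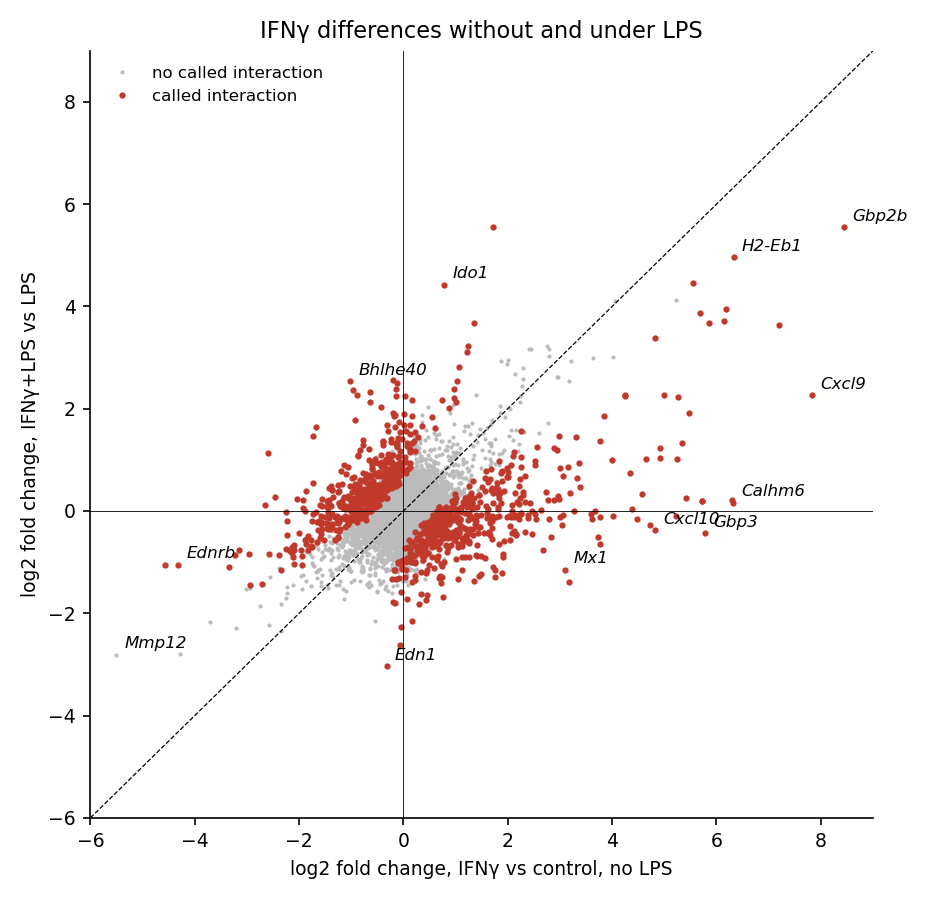
Each dot is 1 of the 7669 genes, at its IFNγ difference without LPS (horizontal, log2 fold change) and under LPS (vertical, log2 fold change); red dots are the 974 genes with a called interaction, and the dashed line marks equal differences. Gbp3 and Calhm6 lie far to the right near 0 on the vertical axis, and H2-Eb1 and Gbp2b lie high on both.

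For IFNβ the interaction was called in 12 genes by limma, 2 positive and 10 negative, with 629 at unadjusted p under 0.05. Ccl5 had an interaction of -5.96 (SE 0.272, adjusted p = 2.73e-08), and Ccl8 of -1.65 (adjusted p = 0.00939), the latter uncalled without IFNβ array 1 (0.0618), IFNβ array 2 (0.089) or LPS array 2 (0.0567), the range over the alternatives being 9.71e-05 to 0.089. The antiviral list had 2 of 32 negative (18 over the list alone, median -0.89, adjusted p = 2.62e-18, 0.0305 estimated), and MHC class I 0 of 19 called by limma (1 over the list alone, median -0.39, adjusted p = 0.00064, 0.0305 estimated). GTPases had 2 of 13 negative (6 over the list alone, median -0.57, adjusted p = 0.000255, adjusted p = 0.131 with an estimated correlation). Cyclic loess called 3 positive and 8 negative, array weights 6 genes, trended robust variances 27, no background correction 22, an offset of 50 20, detection on all 15 arrays 25, and leaving out the 3 doubted arrays 19. The count was 6, 1, 1, 3, 1, 7 and 2 without control array 2, IFNβ array 1, IFNβ array 2, LPS array 1, LPS array 2, IFNβ and LPS array 1, and IFNβ and LPS array 2.

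The 2 interferons shared 65 raised and 7 lowered genes without LPS, where independent lists of those sizes would share 8.41 and 1.89; 2 genes went opposite ways. Under LPS 10 raised and 10 lowered genes were shared against 1.77 and 1.02. Without the 3 doubted arrays 119 genes were shared without LPS and 60 under LPS, and with no detection filter 13 under LPS. Under LPS the overlap was 0 on the slide's 7 arrays and on the compared groups, 1 without LPS array 1, 10 without LPS array 2, and 5 to 55 without each other array. Without LPS it was 76 on the slide's 8 arrays, 31 and 26 without IFNβ array 1 and 2, and 45 without control array 2 or 3. IFNγ and LPS alone shared 532 raised and 760 lowered genes against 188 and 380, with 186 in opposite directions, and IFNβ and LPS alone shared 71 and 7 against 15.49 and 4.42. Each of these pairs shares its control arrays, which are too few to be parted into groups of at least 2, so part of the excess may come from them. The log2 changes of IFNγ and IFNβ without LPS had r = 0.386 across genes, against 0.448 when unchanged groups were simulated against those controls, and a covariance of 0.0840 against 0.0206. Under LPS r was 0.331 against 0.547 and the covariance 0.0628 against 0.0309. For IFNγ and LPS alone r was 0.512 against 0.449 and the covariance 0.479 against 0.0206. The overlaps with LPS alone were not counted again with another normalization. The simulated r comes from unchanged groups alone, while real changes of unequal size alter the observed r. An r below the simulated one thus does not show less agreement. The simulations shared at most 0 calls for each pair, but unchanged groups give few calls in any case, so that is no benchmark either. IFNγ without and under LPS shared 223 raised and 178 lowered genes, where independence would give 60.2 and 66.7. Another 70 were called in opposite directions. Most of these lost the call under LPS on the slide's 7 arrays alone, where 4 of 36 were still called lower and 13 of 34 higher, at unchanged fitted differences.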

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

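The slide-only counts of opposite calls, single genes set against endotoxin, and the tests of mixed material, of LPS alone raising the same genes, of the role of the intermediate array, of endotoxin and of shared controls were chosen after the result was seen.

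The IFNγ difference changed with LPS in 974 genes by a test of the interaction, and the IFNβ difference in 12 genes. Of the former, 70 were called in opposite directions: 36 were higher with IFNγ without LPS and lower under LPS, and 34 the other way. Most of these rest on calls under LPS that the slide's 7 arrays alone do not give. There 4 of the 36 were still called lower and 13 of the 34 higher under LPS, and on the compared groups alone 1 and 11. The fitted differences are the same in these fits. The estimate of the spread differs, and it rests on fewer arrays, which by itself makes a call harder. Examples, chosen after their values were seen, are Mx1 (log2 3.09 without and -1.15 under LPS), Ifit3 (3.17 and -1.38), Bhlhe40 (-1.02 and 2.54) and Klf9 (-0.97 and 2.36). Under LPS Mx1 stood at adjusted p = 0.0475 on the slide alone and 0.0728 on the compared groups (0.000213 to 0.0728 over the alternatives), and Ifit3 at 0.107 and 0.143 (0.000302 to 0.143). Probes without a gene symbol, which the comparisons above do not use, also carried signal: 170 of 654 detected ones were called with IFNγ (82 higher, 88 lower), 12 with IFNβ, 340 with LPS and 102 with IFNγ under LPS.

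Array 1 of IFNγ and LPS lay between its companions and LPS alone. The normalization is argued against as a cause, since the linear share of the way for raised genes was 0.484 to 0.51 over 4 other processings. Of these, the one without background correction used genes parted by over 1 log2 unit; at 1.5 log2 units its share was 0.530 over 70 genes. Mixed material, primed and unprimed, may account for it: on the linear scale raised and lowered genes lay 0.509 and 0.479 of the way, a difference of 0.0302, while on the log2 scale they lay 0.687 and 0.330. A simulated equal mixture gave linear shares of 0.477 and 0.591, a wider gap than the test allowed, so it is not sharp. A lower dose of IFNγ and the mixture cannot be told apart, because the linear share of the 24 most responsive genes exceeded that of the 24 least responsive by 0.0293 with a 95% interval of -0.0336 to 0.125.

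Of the genes raised by IFNγ, 410 had a negative interaction, so their IFNγ difference was smaller under LPS; 54 of these were called higher, 36 lower and 320 neither way under LPS. A ceiling of the signal is argued against, with 3.41% of them within 1 log2 unit of the highest signal, and the intermediate array is argued against as the cause, with 94.6% keeping the negative interaction without it. LPS alone may already raise the same genes: 83.9% of the 410 (344 genes) were called higher with LPS alone, against 39.7% (188) of the 474 other genes raised by IFNγ. That test shares the LPS and control arrays with the interaction, which by itself raises the share. Among genes lowered by IFNγ with a positive interaction, 80.1% (249 of 311) were called lower with LPS alone, against 63.4% (511) of the 806 other genes lowered by IFNγ, a test that shares those arrays too. A slide effect that differs between groups stays open. So does a longer time in culture of the cells with LPS, if those without were harvested at 18 h. A biological change of the IFNγ response also stays open, and was not tested apart from these.

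IFNγ without LPS moved many genes the way LPS moved them. Directions of small changes depend on the normalization here. The median difference over all genes was -0.07 with IFNγ and -0.17 with LPS, against 0.01 and -0.01 with cyclic loess. The shared genes were not counted again with another normalization, so part of the shared falls may come from it. Endotoxin in the interferon that acts as LPS did here is argued against: over the 25 NF-kB genes raised by LPS the median ratio of the IFNγ to the LPS change was 0.0258 (95% interval -0.116 to 0.112), with medians of 0.07 and 2.69 and with 4 genes called higher and 4 lower by IFNγ. Of the single genes raised by LPS that were looked at, some went with endotoxin, the ratio being 0.551 for Il10, 0.370 for Socs3 and 0.268 for Tnf. Others had lower ratios: 0.192 for Ptgs2, 0.0292 for Cxcl2, 0.00745 for Il1b, -0.0128 for Cxcl1, -0.0238 for Il1a and -0.0493 for Saa3. Il6 was undetected in control and IFNγ arrays, so it has no measured ratio. The profile of endotoxin after 18 h was not measured, so a trace that had faded by then stays open. The shared control arrays are argued against as the whole cause, with a covariance of 0.479 across genes against at most 0.0222 in the simulation. A shared interferon programme may remain as a hypothesis, which was not tested.

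For IFNγ against control without LPS, 1 of the 10 splits of the 6 arrays, the real one, called 2025 genes when fitted alone, and the highest of the others was 0. With 3 arrays against 3, 10 splits are too few for a share under 0.05.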

How the results depend on the processing

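Leaving out 3 doubted arrays, array weights, and tests of gene lists on 1 slide alone were tests chosen after seeing the data. The doubted arrays are IFNγ and LPS array 1, which lies between groups, and IFNγ array 1 and IFNβ and LPS array 2. The latter are the dimmest of their slides (median intensity 175 and 143), and their deviations from their groups correlate at 0.435. The next in size, 0.356, pairs IFNγ array 2 with the same IFNβ and LPS group. Deviations within a group depend on each other, so that value is no independent benchmark. In a group of 2 the arrays mirror each other, so the correlation of 0.435 does not say which array of IFNβ and LPS deviates.

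Of 804 results for named genes, 516 kept direction and side of the threshold under each alternative run, slide-only fits apart. Leaving out single arrays apart, 10395 values did so, 477 lost a call, 42 gained one and 1 changed sign: the interaction of Il27 with IFNγ, -1.02, was 0.21 without background correction (adjusted p = 0.413; 0.00269 to 0.413 over the alternatives), and the cause was not tested. With single arrays left out 4047 values kept their side, 690 lost and 7 gained a call. Gene lists were rerun with only some of the alternatives, and not with cyclic loess or with single arrays left out. Among the list values 1272 kept their side, 60 lost and 18 gained a call, slide-only fits apart. In those, over 6 interferon comparisons with 58 list calls, the preset correlation kept 57, lost 1 (chemokines with IFNγ) and gained 2 (inflammatory cytokines with IFNβ, at adjusted p = 0.0371 within 0.0371 to 0.222 over the alternatives, and sterol synthesis between the interferons without LPS). An estimated correlation on the slide alone kept 18 of the 58 and lost 40, among them all 10, 5 and 8 under LPS for IFNγ, IFNβ and IFNγ against IFNβ. Of 29 calls with an estimated correlation on all arrays it kept 17, lost 12 and gained 1 (sterol synthesis with IFNγ). Camera with an estimated correlation takes its degrees of freedom from the arrays fitted, which are few, and fewer on 1 slide. List calls lost that way thus cannot be put down to the correlation between genes alone, and the 2 were not separated.

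With array weights the counts of called genes were 3072 for IFNγ (2001), 195 for IFNβ (86), 16 for IFNβ under LPS (43), 2610 for IFNγ against IFNβ (1582), and 1464 and 6 for the interactions of IFNγ (974) and IFNβ (12). Without the doubted arrays they were 153 for IFNβ, 1982 for IFNγ under LPS (980), 114 for IFNβ under LPS and 19 for the IFNβ interaction, with 6 shared, and the interferons shared 119 (72) calls without LPS and 60 (20) under LPS. On the groups compared alone, where fewer arrays estimate the spread, limma called 203 for IFNγ under LPS, 187 for IFNγ against IFNβ under LPS (1029) and 0 for IFNβ under LPS (654 at unadjusted p under 0.05). On the shared slide alone the counts were 305, 403 and 0 (679 unadjusted). In the interferon comparisons without LPS, the shared slide alone called more genes than all arrays did. Fewer arrays alone therefore need not be the cause, and a larger spread among arrays with LPS was not tested. Without background correction IFNβ under LPS had 65 and the IFNβ interaction 22; an offset of 50 gave the latter 20, trended robust variances 27, and detection on all 15 arrays 25, with 11 for IFNβ under LPS. With no detection filter IFNβ under LPS had 28 and the overlap under LPS 13. The cause of these changes was not tested. The LPS count (4235) stayed within 3205 to 4733.

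Leaving out 1 array at a time gave 1562 to 1883 genes for IFNγ, 31 to 63 for IFNβ, 404 to 1500 for IFNγ under LPS, 1 to 24 for IFNβ under LPS, 862 to 1454 and 520 to 1510 for IFNγ against IFNβ without and under LPS, 640 to 1240 and 1 to 15 for the interactions of IFNγ and IFNβ, and 3455 to 3863 for LPS. A lone array left in a group is assumed to vary like the other groups.

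Whether replicate numbers pair the arrays could not be decided. Over 33 pairs of arrays with one number the deviations correlated at -0.435 to 0.215. Of the arrays, 4 of 15 correlated best with an array of their own number. No expectation for unpaired arrays was computed, and deviations within a small group depend on each other. With the number as a block the IFNβ interaction had 6 genes and 62 named gene results lost their call; the other counts moved less, to 1855, 59, 3996, 685, 29, 1364, 733 and 765 in the order IFNγ, IFNβ, LPS, both under LPS, IFNγ against IFNβ without and under LPS, and the IFNγ interaction. Signal at 1.37 to 1.72 times the background limits calls among dim genes.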

Other observations

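Cyclic loess and median scaling moved the split between genes called higher and lower without moving the count by over 1.5 times. The percentage called higher with IFNγ was 44.2 and became 56.0 with cyclic loess, and with LPS it was 38.4 and became 49.3. For IFNγ against IFNβ under LPS it was 50.9 and became 62.9 with median scaling.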
